A study of Mus musculus with 30 samples.

How the data were processed

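Gene expression was measured with Affymetrix Mouse Gene 1.0 ST arrays on 30 samples of mouse cells. Per the labels, ES cells and the iPS clones ST5 and ST8, of C57BL/6x129SvJae background, were collected at day 0 and day 5 of differentiation with 3 biological replicates each, and E8.25 embryo cells came from Swiss Webster mice. RNA of the cultured cells was extracted with miRNeasy and that of the embryos with RNeasy Micro. The 18 unamplified arrays were labelled with the Affymetrix kit, and 12 further arrays with NuGEN Pico amplification and Encore biotin labelling. Day 0 cells were sorted as Sox2 bright, day 5 cells as Kit positive and Sox2 dim, foregut cells as ENDM1 and Epcam positive with low side scatter, and the comparison cells of the embryo as Epcam positive and ENDM1 negative.

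The deposited values are log2 expression per probe set after RMA, per the submitters' processing notes. The version of RMA is not given, nor whether amplified and unamplified arrays were processed together, so levels were compared within each labelling and not across them. For arrays no read depth exists, and their number limits the precision.

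The deposited data held 35556 probe sets. The annotation listed 23410 of them, 21789 with a single gene and 1621 with several, which were left out of the gene tests together with 12146 that were not listed. Where a gene had more than 1 probe set (999 genes), the one with the highest mean over all arrays was kept, which left 19938 genes. Probe sets could be matched by name to a gene annotation of the mouse genome in 21698 cases (99.6%), which was used for names and neighbours alone. No array or column was left out. Some genes in the lists, T, H19, Mirg, Ddx3y and Gapdh among them, had no probe set of their own.

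Differences were tested with limma 3.58.1 in R 4.3.3, with data.table (version 1.17.8) for reading. A model with a mean per group was fitted to the 18 unamplified arrays (6 groups, 12 residual degrees of freedom) and another to the 12 amplified arrays (4 groups, 8 residual degrees of freedom), with moderated two-sided tests. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes. Contrasts were day 5 against day 0 in each line, the mean of both clones against ES cells at each day, the difference of these responses, ST8 against ST5 at each day, each clone against ES cells, foregut against ENDM1-negative cells and foregut against ES cells at day 5. Standard errors come from these fits and SD from the 3 arrays of a group.

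A total of 30 gene lists were tested with camera, at a preset correlation between genes of 0.01 and again with an estimated correlation, adjusted over the lists of a contrast. They cover pluripotency, epiblast, primitive streak, definitive endoderm, foregut, posterior Cdx and Hox genes, visceral endoderm, parietal endoderm, neural ectoderm, surface ectoderm, mesoderm and heart, endothelium, blood, fibroblast and trophoblast. Others cover maternally and paternally expressed imprinted genes, sex-linked genes, 2-cell and germline genes, glycolysis, cholesterol synthesis, cell cycle, immediate early and heat shock genes, p53 targets, epithelial junctions and keratins, mesenchymal genes, Wnt targets, Nodal and activin targets, BMP targets and DNA methylation machinery. Some genes stand in more than 1 list, though none of the fibroblast markers do. Correlations of responses were taken across genes, which are not independent replicates, and carry no p-value.

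The named genes follow a rule: the 6 largest rises and falls among called genes whose arrays do not overlap between the sides, leaving out provisional and duplicated family symbols, and the 2 largest called rises and falls of each list. It adds the sorting genes Sox2, Kit and Epcam and the markers Pou5f1, Nanog, T, Sox17, Foxa2, Cxcr4, Cer1 and Hhex in every contrast. Between lines it adds Meg3, Rian, Mirg, Dlk1, Rtl1, Dio3, H19, Igf2, Xist, every imprinted gene called in both clones in the same direction and the Y-linked genes. Groups, contrasts, lists, this rule and the alternatives were fixed before the data were examined, with a single exception given below.

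The methods were tested on simulated data with 19938 genes and the group sizes of the study. In the layout of the unamplified arrays, changes of 0.5, 1, 2 and -2 on the log2 scale were recovered in 64%, 98%, 100% and 100% of 50 genes each, and in that of the amplified arrays in 60%, 92%, 100% and 100%. False calls made up 4.737% and 5.376% of calls, and 0 genes were called where no change was put in.

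The alternatives were a fit of all 30 arrays together, a fit of only the groups of a contrast, a further quantile normalization, shifting arrays to a common median and leaving out genes under the median level. Others were the mean of a gene's probe sets or the probe set with the largest spread, an intensity trend with robust spread, the replicate number as a block, a least log2 difference of 1, and leaving out each array in turn. Leaving out ES day 5 replicate 1 and ST8 day 5 replicate 2 together was chosen after seeing the data. A pseudocount was listed too but is not applicable to log2 values. Regroupings of the arrays used 100 draws where more than 100 exist, simulations of shared controls 100 draws, and gene order 1000 permutations, with fixed seeds of 11 and 7.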

Results

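The series asked how closely endoderm made from mouse embryonic stem (ES) cells compares with that from induced pluripotent stem (iPS) cells, the clones ST5 and ST8, and with endoderm of the embryo. iPS cells are body cells returned to a pluripotent state. Definitive endoderm is the germ layer that gives rise to the lining of gut and lung, the liver and the pancreas. RNA was measured on 30 arrays in groups of 3 biological replicates. Labelling without amplification was used for 18 arrays, which hold ES cells, ST5 and ST8 at day 0 and at day 5 of differentiation. Labelling after amplification was used for 12 arrays, which hold ES cells at day 0 and day 5 and cells of the Epcam-positive fraction of E8.25 embryos. The embryo cells were either positive for the endoderm antibody ENDM1 and sorted as foregut, or negative for it and sorted as the comparison population. Day 0 cells were sorted as bright for Sox2, and day 5 cells as positive for Kit and dim for Sox2, so the levels of Sox2, Kit and Epcam are no findings between sorted groups. Array medians lay between 5.5 and 5.57 on the log2 scale without amplification and between 5.69 and 5.74 with it. The number of arrays limits the precision of every value. All differences are log2 differences with their standard error and n = 3 arrays per group.

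ES cells sorted at day 5 had more RNA of endoderm genes and less of most pluripotency genes than ES cells sorted at day 0. The sorting gates differed between the days in every line, so differentiation and the sort cannot be told apart in these contrasts. Cer1, a secreted antagonist of Nodal, BMP and Wnt made by anterior endoderm, rose by 5.05 ± 0.20 (adjusted p = 1.89e-11), from 5.69 ± 0.11 (SD, n = 3) to 10.75 ± 0.27. Cxcr4, the chemokine receptor used to sort definitive endoderm, rose by 4.34 ± 0.33 (adjusted p = 3.1e-08), and the endoderm transcription factors Sox17, Foxa2 and Hhex rose by 2.83 ± 0.50, 2.51 ± 0.29 and 2.98 ± 0.49. The largest rises under the naming rule were those of Amot, a regulator of Hippo signalling, at 5.20 ± 0.28, then Cer1 and Spink1, a secreted trypsin inhibitor, at 4.84 ± 0.37. Dppa5a, an RNA-binding protein of pluripotent cells, fell by 6.34 on the log2 scale (SE 0.20, adjusted p = 1.48e-12), and Fbxo15 and Dnmt3l each fell by 5.33 (SE 0.11 and 0.15).

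Of 24 measured pluripotency genes, 21 fell and 2 rose in ES cells (22 and 2 adjusted over the list alone), and the list moved down against all other genes (camera adjusted p = 1.28e-18, and adjusted p = 0.00099 with an estimated correlation). The risers were Sall4 at 0.47 ± 0.14 and Lin28a at 0.31 ± 0.07. Pou5f1 and Nanog, core factors of pluripotency, changed by -1.78 (SE 0.58, adjusted p = 0.0209) and -2.07 (SE 0.55, adjusted p = 0.00643), far less than Dppa5a. The Pou5f1 call was lost without ES day 5 replicate 1 (adjusted p = 0.0964) and without any of ES day 0 replicates 1, 2 and 3 (0.0514, 0.0508 and 0.051), and the Sall4 call without ES day 5 replicate 1 (0.0619) or when only the ES groups were fitted (0.0573). Of 17 measured definitive endoderm genes, 16 rose (16 adjusted over the list alone), with a median difference of 2.9 (camera adjusted p = 1.21e-10, and adjusted p = 0.209 with an estimated correlation). Of 13 foregut genes 8 rose (8 adjusted over the list alone), among them Isl1 at 3.70 ± 0.33 and the Wnt antagonist Dkk1 at 3.16 ± 0.33 (camera adjusted p = 6.52e-05, and adjusted p = 0.0708 with an estimated correlation). Targets of BMP signalling rose in 6 of 8 cases (6 adjusted over the list alone), led by Id1 at 2.66 ± 0.15 and Id3 at 2.24 ± 0.24 (camera adjusted p = 6.52e-05, and adjusted p = 0.0357 with an estimated correlation).

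Germline genes, the DNA methylation machinery and cell cycle genes fell in ES cells over the same interval. Of 12 genes of the 2-cell stage and germline, 9 fell (9 adjusted over the list alone), with Ddx4, a germ cell RNA helicase, down by -3.43 ± 0.17 and the meiotic gene Sycp3 by -3.40 ± 0.28 (camera adjusted p = 1.41e-06, and adjusted p = 0.0357 with an estimated correlation). Of 10 genes of DNA methylation, 7 fell and 1 rose (7 and 1 adjusted over the list alone): Tet1, which oxidises methylcytosine, changed by -2.45 ± 0.17 and its relative Tet3 by 1.42 ± 0.15 (camera adjusted p = 8.97e-05, and adjusted p = 0.0357 with an estimated correlation). Of 22 cell cycle genes, 20 fell (21 adjusted over the list alone) by a median of -0.43 (camera adjusted p = 2.43e-10, and adjusted p = 0.211 with an estimated correlation). Of 18 fibroblast markers, 15 fell with them (15 adjusted over the list alone), including the collagen cross-linking enzyme Lox at -4.31 ± 0.16 and Dcn at -3.08 ± 0.20 (camera adjusted p = 2.38e-10, and adjusted p = 0.059 with an estimated correlation). Lox stood at 8.19 ± 0.28 (SD, n = 3) on the ES day 0 arrays. Among 19938 genes, limma called 7689 changed, 3765 higher and 3924 lower at day 5, and 1314 of them differed at least 2-fold. With medians made equal 43.6% of calls were higher in place of 49%.

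Both iPS clones went through the same kind of change. Cer1 rose by 4.32 ± 0.20 in ST5 and 3.50 ± 0.20 in ST8, Cxcr4 by 4.08 ± 0.33 and 2.81 ± 0.33, and Sox17 by 2.90 ± 0.50 and 2.07 ± 0.50. Their day 0 means lay higher in ST5 and ST8 than in ES cells: Cer1 at 6.59 and 6.89 against 5.69, Cxcr4 at 7.30 and 7.70 against 6.21, Sox17 at 5.94 and 5.90 against 5.10. Smaller rises therefore do not by themselves show lower day 5 levels. At day 5 Cxcr4 stood at 10.51 in ST8 and 10.54 in ES cells, and Cer1 at 10.39 and 10.75. Spink1 rose by 5.7 ± 0.37 and 4.92 ± 0.37, and Rfx6, a transcription factor of gut and pancreatic endocrine cells, by 6.15 ± 0.50 and 4.76 ± 0.50. Dppa5a changed by -7.30 (SE 0.20) in ST5 and by -6.76 (SE 0.20) in ST8. Nanog changed by -4.63 (SE 0.55, adjusted p = 2.77e-06) in ST5 and by -1.88 (SE 0.55, adjusted p = 0.0114) in ST8, and Pou5f1 by -2.74 (SE 0.58, adjusted p = 0.000736) and -1.59 (SE 0.58, adjusted p = 0.0356). Replicate 2 carried most of both falls in ST8. At day 5 Nanog stood at 6.85 there against 9.93 and 9.84 in the other ST8 arrays, and Pou5f1 at 7.25 against 10.48 and 10.43. The ST8 means at day 0 were 10.76 for Nanog and 10.98 for Pou5f1. In ST8 the Pou5f1 call was lost without ST8 day 5 replicate 2 (adjusted p = 0.0933) and without any of ST8 day 0 replicates 1, 2 and 3 (0.0794, 0.0721 and 0.0782). Lost were also both the Pou5f1 and the Nanog call when only the ST8 groups were fitted (0.188 and 0.108), and with an intensity trend and robust spread that of Pou5f1 (0.0645).

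**Figure D1:**
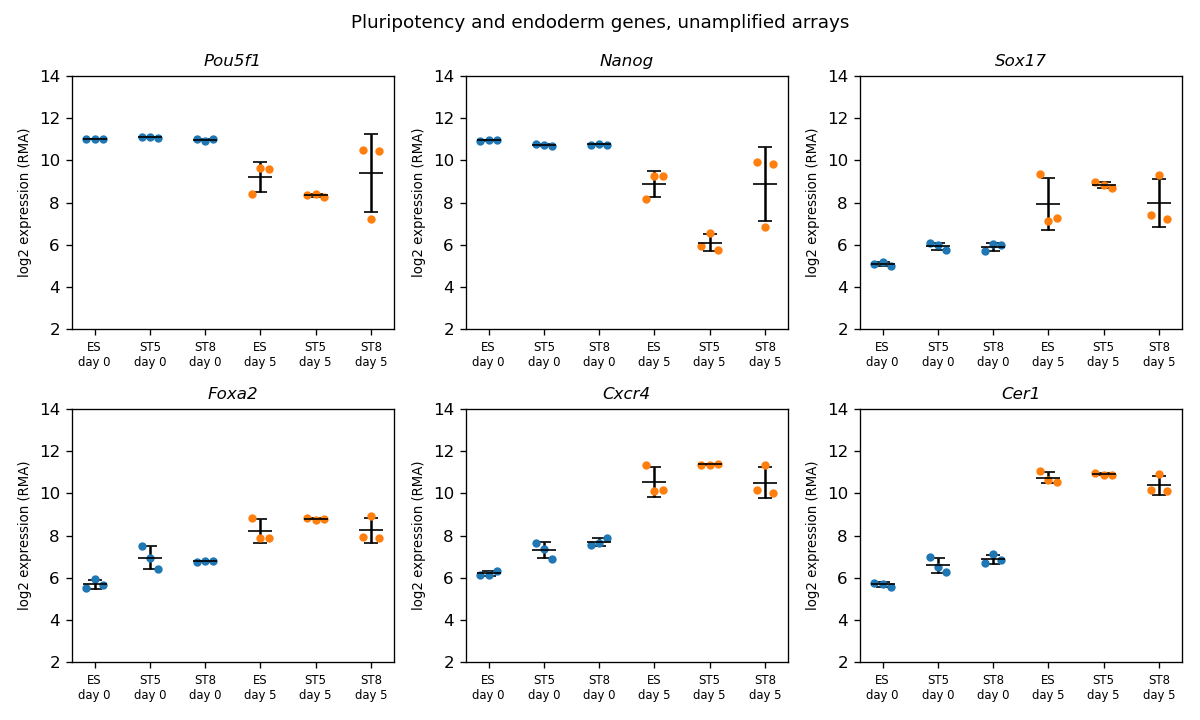
Expression on the log2 scale (vertical axis) of 6 genes on each unamplified array (dots), with the mean and SD of each group of 3 (bars), for ES cells and the clones ST5 and ST8 at day 0 and day 5 (horizontal axis). Cer1 stands at 5.69 in ES cells at day 0 and at 10.75 at day 5, while Pou5f1 at day 5 ranges from 7.25 to 10.48 among the ST8 arrays.

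Of the 17 definitive endoderm genes, 17 rose in ST5 and 16 in ST8 (17 in each adjusted over the list alone; camera adjusted p = 7.43e-11 and 5.51e-10, and adjusted p = 0.178 and 0.222 with an estimated correlation). Of the 24 pluripotency genes, 22 fell and 1 rose in either clone (22 and 1 adjusted over the list alone; camera adjusted p = 2.2e-14 and 3.43e-17, and adjusted p = 0.00328 and 0.00144 with an estimated correlation). Genes of epithelial junctions and keratins rose in 13 of 14 cases in ST5 (13 adjusted over the list alone) and 11 in ST8 (12), with Krt18 at 4.22 ± 0.20 and 3.35 ± 0.20 (camera adjusted p = 2.05e-08 and 3.08e-07, and adjusted p = 0.176 and 0.222 with an estimated correlation). Fibroblast markers fell as in ES cells, 17 of 18 in ST5 and 15 in ST8 (17 and 16 adjusted over the list alone; camera adjusted p = 1.03e-10 and 4.14e-12, and adjusted p = 0.0686 and 0.0433 with an estimated correlation).

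With limma, 9560 genes changed in ST5 (4621 higher, 4939 lower; 2210 at least 2-fold) and 8074 in ST8 (4178 higher, 3896 lower; 1437 at least 2-fold). In ST5 43% of calls were higher after a further quantile normalization in place of 48.3%. Across genes, which are not independent replicates, the ES response correlated with that of ST5 at r = 0.872 and with that of ST8 at r = 0.923. Among 6331 genes called in both ES cells and ST5, 6269 moved in the same direction, 3002 up against 873 for independent lists and 3267 down against 972. For ES cells and ST8 the direction was the same for 6213 of 6231 genes. All 3 lines shared 2742 genes that rose and 2852 that fell, of which 537 and 438 moved at least 2-fold in every line.

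Before differentiation, the iPS clones differed from ES cells in a group of noncoding RNAs transcribed from the maternal copy of the imprinted Dlk1-Dio3 domain. Imprinted genes are read from the copy of a single parent. Rian was lower in iPS cells by -3.67 ± 0.13 (adjusted p = 4.33e-11) and Meg3 by -2.65 ± 0.09 (adjusted p = 1.24e-11), and the transcripts DQ267102 and DQ267101 by -3.40 ± 0.09 and -2.57 ± 0.15. Meg3 stood at 10.24 ± 0.10 (SD, n = 3) in ES cells, 7.56 ± 0.05 in ST5 and 7.62 ± 0.13 in ST8. The protein-coding genes of the domain, which are read from the paternal copy, differed little: Rtl1 by -0.37 ± 0.09 (adjusted p = 0.026), with Dlk1 at -0.06 ± 0.14 and Dio3 at -0.17 ± 0.09 not passing the test. In ES cells at day 0 Dio3 stood at 4.39, under the array medians, Rtl1 at 5.66, near them, and Dlk1 at 6.55. Such low levels, of Dio3 and Rtl1 above all, limit how far a fall could show. The Rtl1 call was lost without ES day 0 replicates 1, 2 or 3 (adjusted p = 0.134, 0.0985 and 0.0652), ST5 replicate 1 (0.0503) or ST8 replicate 2 (0.0553).

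Other imprinted genes moved both ways at day 0. Nnat, Zdbf2 and Slc38a4, all read from the paternal copy, were lower in iPS cells by -0.98 ± 0.10, -1.39 ± 0.13 and -0.83 ± 0.10, while Peg10 and Peg3 were higher by 0.61 ± 0.13 and 0.57 ± 0.12. These are means over the clones: Nnat stood at 6.56 in ES cells, 6.22 in ST5 and 4.95 in ST8, and Peg10 differed from ES cells by 0.28 in ST5 and 0.94 in ST8. The call for Peg10 was lost without ES day 0 replicate 3 (adjusted p = 0.0587), and that for Peg3 without ES day 0 replicate 1 (0.0503) or 3 (0.0526). Of 24 measured paternally expressed genes 4 rose and 4 fell (4 and 4 adjusted over the list alone; camera adjusted p = 0.977). Of 16 maternally expressed genes 1 rose and 3 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.209). Igf2, at 0.05 ± 0.14, did not pass the test.

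**Figure D2:**
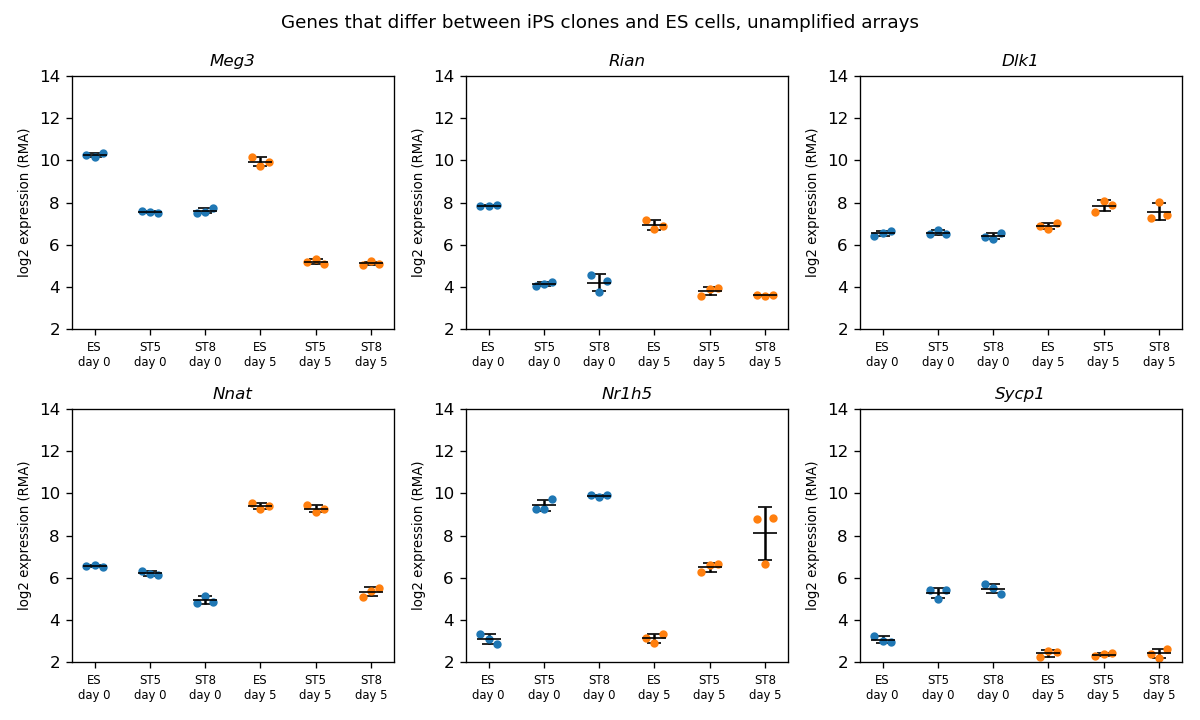
Expression on the log2 scale (vertical axis) of 6 genes on each unamplified array (dots), with the mean and SD of each group of 3 (bars), for ES cells and the clones ST5 and ST8 at day 0 and day 5 (horizontal axis). Meg3 lies at 10.24 in ES cells and at 7.56 and 7.62 in the clones at day 0, and Nnat at day 5 lies at 5.35 in ST8 against 9.41 in ES cells.

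The largest difference at day 0 was that of Nr1h5, which encodes a nuclear receptor: it was higher in iPS cells by 6.55 ± 0.34 (adjusted p = 5.76e-09), at 3.10 ± 0.23 (SD, n = 3) in ES cells against 9.43 ± 0.28 in ST5 and 9.88 ± 0.05 in ST8. Sycp1, a component of the meiotic synaptonemal complex, was higher by 2.32 ± 0.12 (adjusted p = 7.97e-09). Targets of Wnt signalling were higher as a group, 5 of 9 measured (5 adjusted over the list alone), including Sp5 at 1.36 ± 0.07 and Lef1 at 1.07 ± 0.13 (camera adjusted p = 6.82e-08, and adjusted p = 0.00811 with an estimated correlation). Of 15 primitive streak genes, which mark the cells that form mesoderm and endoderm, 7 were higher and 2 lower (8 and 2 adjusted over the list alone), with Mixl1 at 1.97 ± 0.25 and Eomes at 1.59 ± 0.19 (camera adjusted p = 0.000143, and adjusted p = 0.138 with an estimated correlation). Bmp4 and the retinoic acid hydroxylase Cyp26a1 were higher by 1.81 ± 0.20 and 2.26 ± 0.28. Epithelial genes were lower in 4 of 14 cases (6 adjusted over the list alone), with Cldn4 at -0.89 ± 0.11 (camera adjusted p = 3.96e-05, and adjusted p = 0.634 with an estimated correlation).

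Pluripotency genes showed no shift as a list at day 0: 1 of 24 was higher and 2 lower (3 and 2 adjusted over the list alone; camera adjusted p = 0.625). Zfp42 was lower in iPS cells by -1.36 ± 0.23 and Fgf4 by -0.50 ± 0.09, while Pou5f1 differed by 0.04 ± 0.50 and Nanog by -0.21 ± 0.48, neither passing the test. The fit shares its spread with the day 5 arrays, where Nanog had an SD of 1.76 in ST8, against 0.03 to 0.04 at day 0. With the day 0 groups alone Nanog passed (adjusted p = 0.0246) and Pou5f1 did not (0.73). Of 18 fibroblast markers 1 was higher (2 adjusted over the list alone), Lum at 0.70 ± 0.16 (camera adjusted p = 0.103), a call lost without ES day 0 replicate 1 (adjusted p = 0.104) or 2 (0.124). Mesenchymal genes shifted up in iPS cells (camera adjusted p = 0.0254). Immediate early and heat shock genes and p53 targets shifted down (camera adjusted p = 0.0143 and 0.00577). All of these list calls were lost with an estimated correlation (adjusted p = 0.843, 0.618 and 0.843). In all, limma called 971 genes, 448 higher and 523 lower in iPS cells, and 52 at least 2-fold. The balance depended on the scaling, with 341 higher and 595 lower when medians were made equal (36.4% higher in place of 46.1%) and 449 and 653 after a further quantile normalization (40.7%). The count dropped to 489, 530 and 503 without ES day 0 replicate 1, 2 or 3, and was 1737 when only the day 0 groups were fitted. At either day, the p-values of limma measure the spread between replicates of a line, pooled over the 6 groups of both days. For a gene that varies more at day 5, as Nanog does, the pooled spread understates that at day 5 and overstates that at day 0. The labels name no further ES line, so traits of these lines cannot be told apart from a general difference between iPS and ES cells.

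Each clone on its own gave a similar contrast with ES cells at day 0, with 643 genes called in ST5 and 707 in ST8. Both clones shared 376 of them in the same direction, 171 higher against 5.17 for independent lists and 205 lower against 6.15, with no gene called in opposite directions by limma. The clones are set against the same 3 ES arrays, and simulated unchanged groups sharing those arrays gave at most 0 shared calls in 100 draws. The simulation drew independent genes without any change, so hardly any call could arise and its count does not weigh for the shared calls. Across genes, which are not independent replicates, the differences of the clones from ES cells correlated at 0.81 at day 0 and 0.503 at day 5, where the shared ES arrays alone gave 0.499 in simulation. The covariance at day 5 was 0.0342 against 0.00846 in simulation. The shared count was 208, 232 and 194 without ES replicate 1, 2 or 3, 219 and 244 without ST8 replicates 1 and 3, and 734 with the day 0 groups alone. At day 5, 4653 genes were called between ST5 and ES cells and 191 between ST8 and ES cells, 140 of them shared in one direction and 1 in opposite directions. Of the shared genes 55 were higher against 9.13 for independent lists and 85 lower against 13.2. Simulated unchanged groups gave at most 1 shared call in 100 draws, a count that by the same construction carries no weight. That shared count was 826, 83 and 69 without ES day 5 replicate 1, 2 or 3, 89 and 253 without ST8 day 5 replicates 1 and 2, 88 with dim genes left out and 30 with the day 5 groups alone.

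By day 5 the difference in Meg3 had widened. Meg3 was lower in the iPS clones by -4.79 ± 0.09 (adjusted p = 2.24e-15), at 9.95 ± 0.21 (SD, n = 3) in ES cells against 5.20 ± 0.11 in ST5 and 5.12 ± 0.09 in ST8, and Rian was lower by -3.22 ± 0.13. Nnat was lower by -2.10 ± 0.10 on average over the clones, with ST8 at 5.35 and ST5 at 9.27 against 9.41 in ES cells, and Dlk1 was higher by 0.81 ± 0.14 (adjusted p = 0.00432). Nr1h5 remained higher in iPS cells, by 4.17 ± 0.34, and Tgfb2, a growth factor of the TGF-beta family, was lower by -1.75 ± 0.16. Genes of yolk sac endoderm and liver secretion were higher in iPS cells for Ttr, a thyroid hormone carrier, at 1.68 ± 0.25 (9.05 in ST5 and 6.83 in ST8 against 6.26 in ES cells), Apob at 1.20 ± 0.17 and the retinol carrier Rbp4 at 1.84 ± 0.34. That visceral endoderm list had 4 of 19 members higher (7 higher and 2 lower adjusted over the list alone; camera adjusted p = 0.0055, and adjusted p = 0.786 with an estimated correlation), and its call was lost with dim genes left out (0.214). The calls for Ttr, Apob, Rbp4 and Dlk1 were lost when only the day 5 groups were fitted (adjusted p = 0.0526, 0.0526, 0.0888 and 0.068), and that for Rbp4 also without ES day 5 replicate 2 (0.0534) or 3 (0.0628).

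Averaged over the clones, the endoderm markers named here did not pass the test against ES cells at day 5. Sox17 differed by 0.48 ± 0.43, Foxa2 by 0.31 ± 0.25, Cxcr4 by 0.40 ± 0.28 and Cer1 by -0.09 ± 0.18. ST5 had the higher levels, with Sox17 at 8.84 ± 0.15 (SD, n = 3) against 7.93 ± 1.23 in ES cells and 7.98 ± 1.15 in ST8, and Cxcr4 at 11.38 ± 0.03 against 10.54 ± 0.71 and 10.51 ± 0.74. ES replicate 1 raised the ES means, with Sox17 at 9.35 against 7.15 and 7.28 and Cxcr4 at 11.37 against 10.12 and 10.14. ST8 replicate 2 did so in ST8, with Sox17 at 9.30 against 7.40 and 7.23 and Cxcr4 at 11.36 against 10.14 and 10.02. Without ES day 5 replicate 1 and ST8 day 5 replicate 2, a setting chosen after seeing the data, Sox17 and Cxcr4 passed as higher in the mean of the clones than in ES cells. That setting drops the highest ES array for both genes, which lowers the ES mean by construction. The ST8 arrays left lay near the ES arrays left for both genes, so the difference was carried by ST5. Of 17 definitive endoderm genes, 6 were higher and 1 lower in ST5 than in ES cells (11 and 1 adjusted over the list alone; camera adjusted p = 0.000959, and adjusted p = 0.565 with an estimated correlation). ST8 against ES cells had 0 called (0 adjusted over the list alone; camera adjusted p = 0.524). ST8 against ST5 had 1 higher and 2 lower (1 and 2 adjusted over the list alone; camera adjusted p = 0.00134, downward, and adjusted p = 0.758 with an estimated correlation). The definitive endoderm list shifted upward in iPS cells with a median of 0.49, although its single called member, the keratin gene Krt19, was lower by -0.82 ± 0.19 (-1.25 in ST5 and -0.40 in ST8). Of its 17 genes 1 was lower (1 adjusted over the list alone; camera adjusted p = 0.00728, and adjusted p = 0.795 with an estimated correlation). The Krt19 call was lost without ES day 5 replicate 2 (adjusted p = 0.0892) or 3 (0.0987). The list lost its call without either of them (0.127 and 0.157), without ST8 day 5 replicate 2 (0.105) or with dim genes left out (0.217). Fibroblast markers were lower in 6 of 18 cases (6 adjusted over the list alone; camera adjusted p = 0.000642, and adjusted p = 0.786 with an estimated correlation). Mesenchymal genes were lower in 2 of 10 (5 adjusted over the list alone; camera adjusted p = 0.0175, and adjusted p = 0.786 with an estimated correlation). That call was lost without ES day 5 replicate 2 (0.0842) or 3 (0.0808).

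Arrays within the day 5 groups stood apart from each other, and the counts followed them. On the leading principal component of the day 5 arrays, which held 66.3% of the variance, ES replicate 1 lay at 6.8 against -30.9 and -29.5 for the other ES arrays. ST8 replicate 2 lay at 22.6 against -26.7 and -26.9, near the ST5 arrays at 26.4 to 30.4. limma called 1714 genes between iPS and ES cells at day 5, 859 higher and 855 lower, 94 of them at least 2-fold. After a further quantile normalization 35.5% of calls were higher in place of 50.1%, and with dim genes left out 63.4%. The count became 4461 without ES replicate 1, 322 without ES replicate 2, 233 without ES replicate 3, and 947, 1068 and 1128 without ST5 replicate 1, 2 or 3. It was 140 when only the day 5 groups were fitted, where 37 of the 50 named calls were lost, while Meg3, Rian, Nnat, Nr1h5 and Tgfb2 kept theirs.

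Tested as a difference between responses, the change from day 0 to day 5 ran lower in iPS cells than in ES cells for genes of the primitive streak and for Wnt targets, some of which had started higher in iPS cells. The lower responses of Sp5, Mixl1 and Eomes about match their higher start, so they do not show lower levels at day 5. For Sp5 the response was lower by -1.46 ± 0.10 (adjusted p = 9.87e-07), for Lgr5, a receptor of Wnt-enhancing R-spondins, by -1.64 ± 0.24, for Mixl1 by -1.91 ± 0.36, for Eomes by -1.57 ± 0.27 and for the cadherin Cdh2 by -1.99 ± 0.33. Of 9 Wnt targets 5 responded lower (5 adjusted over the list alone; camera adjusted p = 7.24e-07, and adjusted p = 0.0171 with an estimated correlation). Of 15 primitive streak genes 5 responded lower and 1 higher (8 and 2 adjusted over the list alone; camera adjusted p = 0.000269, and adjusted p = 0.26 with an estimated correlation). Epithelial genes responded higher in 5 of 14 cases (10 adjusted over the list alone), with Cldn7 at 1.37 ± 0.26 (camera adjusted p = 3.29e-10, and adjusted p = 0.26 with an estimated correlation). The Cldn7 call was lost without ES day 5 replicate 3 (adjusted p = 0.0539). Meg3 responded lower by -2.14 ± 0.12 and Sycp1 by -2.36 ± 0.18. Sycp1 stood at 3.07 in ES cells, 5.29 in ST5 and 5.49 in ST8 at day 0, and at 2.43, 2.37 and 2.42 at day 5. The clone mean for Nnat was -1.13 ± 0.15, but Nnat went from 6.56 to 9.41 in ES cells, from 6.22 to 9.27 in ST5 and from 4.95 to 5.35 in ST8, so the lower mean was carried by ST8. The responses of the clones were not tested against each other. In fibroblast markers 2 of 18 responded lower (9 adjusted over the list alone; camera adjusted p = 2.62e-06, and adjusted p = 0.26 with an estimated correlation).

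In total 427 genes differed in response, 217 higher and 210 lower in iPS cells, 71 of them by at least 2-fold. This balance moved with the setting, to 315 higher and 183 lower with dim genes left out (63.3% higher in place of 50.8%), 238 and 174 with medians made equal, and 211 and 233 after a further quantile normalization. The count became 1744 without ES day 5 replicate 1, 191 and 173 without ES day 5 replicates 2 and 3, and 673 without ST8 day 5 replicate 2. It became 198 and 173 without ES day 0 replicates 1 and 3, and 280 and 252 without ST8 day 0 replicates 1 and 3.

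Few genes separated the clones before differentiation. Between them limma called 13 at day 0, 10 higher and 3 lower in ST8, and 1574 genes had an unadjusted p under 0.05. Nnat was lower in ST8 by -1.27 ± 0.12 (adjusted p = 0.000222) and was the only gene past 2-fold, at 4.95 ± 0.18 (SD, n = 3) against 6.22 ± 0.11 in ST5. Plekhg5 and Nol9 were higher by 0.80 ± 0.10 and 0.74 ± 0.08. Meg3 and Rian did not separate the clones, at 0.06 ± 0.10 and 0.05 ± 0.15. The share of calls that were higher in ST8 was 76.9%, against 57.1% after a further quantile normalization and 55.6% with medians made equal. Leaving out ST5 replicate 1, 2 or 3 gave 5, 3 and 21 genes, leaving out ST8 replicate 1, 2 or 3 gave 4, 4 and 3, and the fit on these groups alone gave 6. The replicate block gave 5. Of 10 named calls, 6 were lost with these groups alone and 5 with the replicate block.

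Camera called gene lists between the clones at day 0, all of them lost with an estimated correlation. Primitive streak genes were lower in ST8, with 0 of 15 called by limma (1 lower adjusted over the list alone; camera adjusted p = 0.00016, and adjusted p = 0.158 with an estimated correlation). DNA methylation genes were higher, with 0 of 10 called by limma (2 higher adjusted over the list alone; camera adjusted p = 0.00244, and adjusted p = 0.158 with an estimated correlation). Maternally expressed imprinted genes were higher in 2 of 16 cases (2 adjusted over the list alone; camera adjusted p = 0.0101, and adjusted p = 0.313 with an estimated correlation), a list call lost without ST5 replicate 3 (0.0744). Surface ectoderm and germline genes ran lower and glycolysis genes higher, with 0 of 10, 0 of 12 and 0 of 16 called by limma (1, 0 and 0 adjusted over the list alone; camera adjusted p = 0.026 each, and adjusted p = 0.313, 0.313 and 0.713 with an estimated correlation). These last calls were also lost with dim genes left out (0.556, 0.255 and 0.255) and without single arrays.

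At day 5, Nnat differed more between the clones, by -3.92 ± 0.12 (adjusted p = 8.62e-12), standing at 9.27 ± 0.17 (SD, n = 3) in ST5 and 5.35 ± 0.22 in ST8. ST8 had higher Tdgf1, a Nodal co-receptor, by 3.02 ± 0.64, higher Nanog by 2.76 ± 0.55 and higher Utf1 by 2.95 ± 0.53, and lower Ttr by -2.22 ± 0.29. Paternally expressed imprinted genes were lower in ST8 in 8 of 24 cases and higher in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 6.72e-05, and adjusted p = 0.403 with an estimated correlation). limma called 2909 genes, 1652 higher and 1257 lower in ST8, 258 of them at least 2-fold, and 66.1% were higher with medians made equal in place of 56.8%. That count became 5951 without ST8 replicate 2, 714 and 675 without ST8 replicates 1 and 3, and 1295, 1453 and 1288 without ST5 replicates 1, 2 and 3. It was 3 when only these groups were fitted, where 62 of the 63 named calls were lost and that of Nnat was kept. Adjusted p values were then 0.136 for Tdgf1 and Nanog, 0.123 for Utf1 and 0.0851 for Ttr. The Tdgf1 call was also lost without ST8 replicate 1 (adjusted p = 0.0546) or 3 (0.0554).

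ES cells measured again after amplification gave the same picture. Spink1 rose by 4.91 ± 0.17, Cer1 by 4.51 ± 0.26, Cxcr4 by 3.33 ± 0.23 and Foxa2 by 2 ± 0.15, while Fbxo15 changed by -5.89 (SE 0.21) and Dppa5a by -5.61 (SE 0.27). Bmp2, a secreted signal of the BMP family, rose by 4.23 ± 0.15. Of 17 definitive endoderm genes 16 rose (17 adjusted over the list alone; camera adjusted p = 8.99e-17, and adjusted p = 0.0739 with an estimated correlation). Of 24 pluripotency genes 21 fell and 1 rose (21 and 2 adjusted over the list alone; camera adjusted p = 2.96e-18, and adjusted p = 0.00167 with an estimated correlation). Fibroblast markers fell in 13 of 18 cases (15 adjusted over the list alone), with S100a4 down by -4.04 ± 0.14 (camera adjusted p = 1.11e-09, and adjusted p = 0.0505 with an estimated correlation). limma called 5354 genes, 2596 higher and 2758 lower, 933 of them at least 2-fold. Across genes the responses with and without amplification correlated at r = 0.892 with a slope of 0.783, and 4607 of 4615 genes called in both moved in the same direction.

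In the embryo, foregut cells carried the markers of endoderm, and the ENDM1-negative cells those of ectoderm and blood vessels. Ttr was higher in foregut by 3.69 ± 0.31 (adjusted p = 1.56e-05), at 11.52 ± 0.37 (SD, n = 3) against 7.83 ± 0.56. The peptide hormone genes Pyy and Trh were higher by 3.33 ± 0.44 and 2.55 ± 0.07, and the endoderm factors Foxa2 and Hhex by 1.25 ± 0.15 and 1.66 ± 0.28. Tfap2a and Dlx5, transcription factors of surface ectoderm and neural crest, were lower in foregut by -3.19 ± 0.17 and -2.78 ± 0.16, Cdh5, the cadherin of endothelial cells, by -2.71 ± 0.14, and Pax6, a factor of neural ectoderm and eye, by -2.04 ± 0.18. Pou5f1 was lower by -2.25 ± 0.32, and Sox17 differed by 0.97 ± 0.34 without passing the test (adjusted p = 0.106), although it passed with these groups fitted alone.

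Of 13 foregut genes 10 were higher (11 adjusted over the list alone; camera adjusted p = 1.55e-13, and adjusted p = 0.00982 with an estimated correlation). Definitive endoderm genes were higher in 14 of 17 cases (16 adjusted over the list alone; camera adjusted p = 6.38e-18, and adjusted p = 0.0461 with an estimated correlation). Visceral endoderm genes were higher in 16 of 19 (18, with 1 lower, adjusted over the list alone; camera adjusted p = 1.33e-18, and adjusted p = 0.0435 with an estimated correlation). Surface ectoderm genes were lower in 7 of 10 (7 adjusted over the list alone; camera adjusted p = 6.93e-10, and adjusted p = 0.00982 with an estimated correlation). Endothelial genes were lower in 7 of 10 (8 adjusted over the list alone; camera adjusted p = 1.37e-11, and adjusted p = 0.0303 with an estimated correlation). Neural genes were lower in 4 of 18 (6 adjusted over the list alone; camera adjusted p = 8.98e-05, and adjusted p = 0.0343 with an estimated correlation). Pluripotency genes were lower in 9 of 24 cases and higher in 1 (10 and 1 adjusted over the list alone; camera adjusted p = 3.03e-05, and adjusted p = 0.0343 with an estimated correlation). Maternally expressed imprinted genes were higher in 7 of 16 and lower in 1 (7 and 2 adjusted over the list alone), among them the growth inhibitor Cdkn1c at 1.48 ± 0.12 and Zim1 at 2.06 ± 0.16 (camera adjusted p = 3.03e-05, and adjusted p = 0.0435 with an estimated correlation). With dim genes left out, the list calls for endothelial genes (adjusted p = 0.957, upward) and neural genes (0.944) were lost. limma called 1623 genes, 740 higher and 883 lower in foregut, 266 of them at least 2-fold. The balance turned after a further quantile normalization, to 832 higher and 667 lower (55.5% higher in place of 45.6%), and was 38.8% higher with dim genes left out. The count became 985 without foregut replicate 1 and 1069 without ENDM1-negative replicate 1, and 2467 when all 30 arrays were fitted together.

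**Figure D3:**
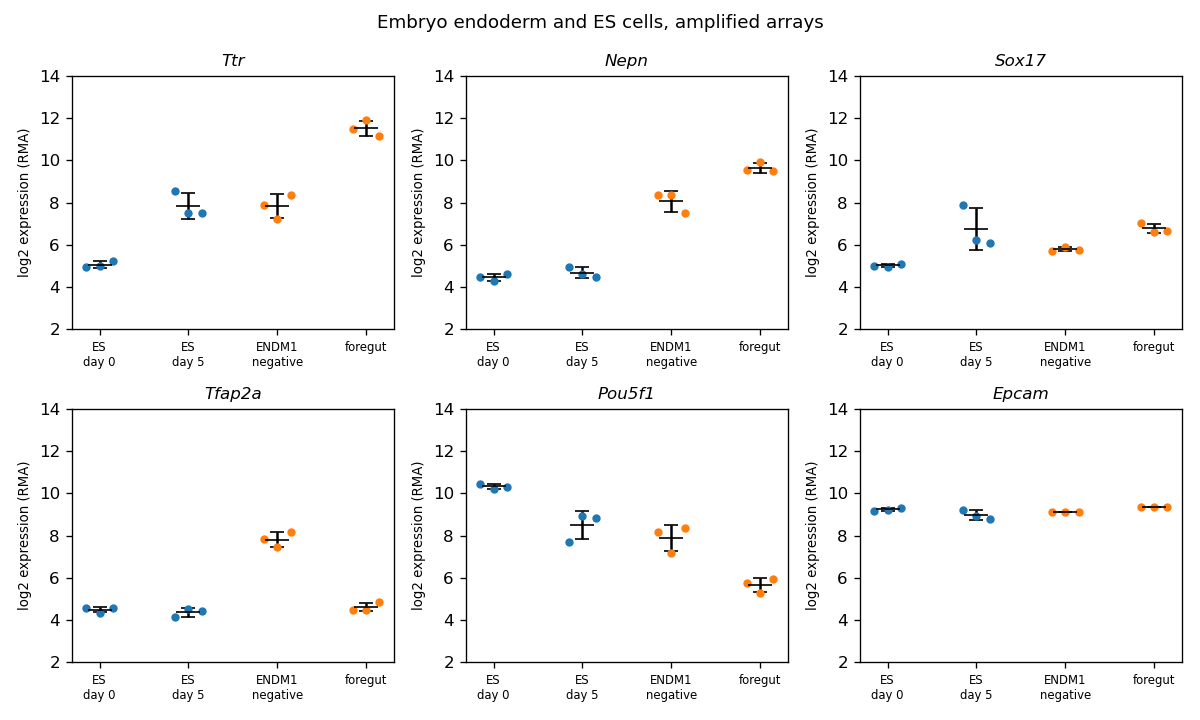
Expression on the log2 scale (vertical axis) of 6 genes on each amplified array (dots), with the mean and SD of each group of 3 (bars), for ES cells at day 0 and day 5 and for ENDM1-negative and foregut cells of the embryo (horizontal axis). Ttr stands at 11.52 in foregut against 7.86 in ES cells at day 5, and Nepn at 9.64 against 4.69.

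Set directly against ES-derived day 5 cells, foregut had less RNA from Nodal targets and from single genes of the anterior streak, and more from posterior Cdx and Hox genes. Tdgf1 was lower in foregut by -6.25 ± 0.41 (adjusted p = 6.48e-07), Nanog by -2.16 ± 0.32, the anterior streak genes Eomes and Lhx1 by -2.95 ± 0.25 and -3.01 ± 0.22, and Cer1 by -2.75 ± 0.26. Targets of Nodal and activin were lower in foregut in 7 of 9 cases (7 adjusted over the list alone; camera adjusted p = 2.86e-08, and adjusted p = 0.00742 with an estimated correlation). The extracellular proteoglycan gene Nepn was higher in foregut by 4.95 ± 0.21 (adjusted p = 2.48e-08), Afp, a carrier protein of fetal liver and yolk sac, by 3.68 ± 0.32, Pax9, a factor of the pharyngeal endoderm, by 2.14 ± 0.12, and Cdx4, a factor of the posterior embryo, by 3 ± 0.13. Sox17 and Hhex did not pass the test, at 0.03 ± 0.34 and -0.69 ± 0.28.

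Cdx and Hox genes of the posterior body were higher in foregut in 10 of 11 cases (11 adjusted over the list alone; camera adjusted p = 8.56e-08, and adjusted p = 0.047 with an estimated correlation). That call was lost with dim genes left out (0.0646). Against ENDM1-negative cells the same list was lower in foregut (camera adjusted p = 0.00597, and adjusted p = 0.151 with an estimated correlation). With dim genes left out the latter call was lost too (0.616). Visceral endoderm genes were higher in 16 of 19 (16 adjusted over the list alone; camera adjusted p = 1.7e-09, and adjusted p = 0.199 with an estimated correlation). The definitive endoderm list had 5 of 17 higher and 3 lower (5 and 3 adjusted over the list alone; camera adjusted p = 0.991), and the foregut list 5 of 13 higher and 2 lower (6 and 2 adjusted over the list alone; camera adjusted p = 0.167). Epiblast genes were lower in 5 of 11 cases (5 adjusted over the list alone; camera adjusted p = 0.0013, and adjusted p = 0.199 with an estimated correlation). Of 15 primitive streak genes 6 were lower and 2 higher (7 and 3 adjusted over the list alone), with a median of 0.02 against a mean of -0.62 (camera adjusted p = 0.0135, and adjusted p = 0.265 with an estimated correlation). That primitive streak call was lost with dim genes left out (0.0843). Cholesterol synthesis genes were lower in 10 of 18 cases (13 lower and 1 higher adjusted over the list alone), with Msmo1 at -1.56 ± 0.15 (camera adjusted p = 8.85e-08, and adjusted p = 0.26 with an estimated correlation). Targets of p53 were lower in 7 of 11 (8 adjusted over the list alone), with Ccng1 at -1.85 ± 0.15 (camera adjusted p = 3.69e-07, and adjusted p = 0.0531 with an estimated correlation). The embryonic globins Hbb-bh1 and Hba-x were higher in foregut by 4.10 ± 0.16 and 2.76 ± 0.22, but the blood list had 3 of 10 higher and 1 lower and did not pass (3 and 1 adjusted over the list alone; camera adjusted p = 0.192). Xist, the RNA of the inactive X of female cells, was higher by 4.36 ± 0.14. limma called 4817 genes, 2939 higher and 1878 lower in foregut, 611 of them at least 2-fold. After a further quantile normalization 71.3% of calls were higher in place of 61%, with a median shift over all genes of 0.126 against 0.076. Embryo and ES cells differed in mouse strain, RNA extraction kit and sorting gate as well as in origin, and these cannot be told apart here. Sex may differ as well, given the Xist value, and was not tested.

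The change from ES cell to day 5 endoderm and the difference between foregut and ENDM1-negative cells, which share no array, correlated across genes at r = 0.343. Of 972 genes called in both, 875 had the same direction, 385 up against 96.4 for independent lists and 490 down against 122. Cer1, Cxcr4, Foxa2, Hhex and Spink1 were higher in both, Cxcr4 by 1.04 ± 0.23 in foregut (adjusted p = 0.0159), a call lost without foregut replicate 1 (0.0591) or 2 (0.0625) and ENDM1-negative replicate 1 (0.0554) or 3 (0.057). The other 97 genes went opposite ways.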

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

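The split counts here were chosen before the results were seen, and the tests of single-array labelling, of a variant under the probes and of loss of the whole domain only after.

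The response to differentiation differed between iPS and ES cells for 427 genes in a test of the difference itself. By that test the response ran higher in iPS cells for Ptk2b (0.69), Hpf1 (0.36), Klf4 (0.77), Nodal (0.68), Ttr (1.86), Apob (1.25), Lhx2 (0.72), Phlda2 (0.57), Zdbf2 (0.97), Dlk1 (0.87), Mcm4 (0.32), Cldn7 (1.37), Grhl2 (1.15), Tet2 (0.90) and the sorting gene Epcam (0.56). It ran lower for Mcc (-1.58), Mc5r (-0.74), Slc5a6 (-0.73), Sema5a (-0.70), Dppa3 (-0.80), Lef1 (-1.21), Mixl1 (-1.91), Eomes (-1.57), Cer1 (-1.14), Trf (-0.89), Apoa2 (-0.60), Sox11 (-0.81), Col1a1 (-0.60), Col6a3 (-0.47), Meg3 (-2.14), Nnat (-1.13), Peg10 (-0.74), Sycp1 (-2.36), Cdh2 (-1.99), Lgr5 (-1.64) and Sp5 (-1.46). Of these 36 calls, 12 were lost without ES day 5 replicate 2, 12 without ES day 5 replicate 3, and 12, 9 and 11 without ES day 0 replicates 1, 2 and 3. Lost without at least 1 single array were those of Cer1, Cldn7, Col1a1, Col6a3, Dlk1, Epcam, Grhl2, Hpf1, Klf4, Lhx2, Mcm4, Peg10 and Sema5a, and with all 30 arrays those of Apoa2, Apob and Phlda2. Lower responses of Sp5, Mixl1, Eomes, Cer1 and Sycp1 go with a higher level in iPS cells at day 0. The values are means over the clones, and for some genes a single clone carries them. Nnat went from 6.56 to 9.41 in ES cells and from 6.22 to 9.27 in ST5, but from 4.95 to 5.35 in ST8. The response of Peg10 was 1.08 in ES cells, 1.04 in ST5 and -0.35 in ST8. ST5 carries the value of Klf4 (-3.01 in ES cells, -1.44 in ST5, -3.03 in ST8) and the larger part of those of Grhl2 (-0.51, 1.21 and 0.08) and Ttr (1.52, 4.44 and 2.32). With the line labels redrawn within each day, 4 of 100 groupings gave as many genes as the real one, which gave 197 in that layout against a highest other of 574. That share lies just under 0.05 and was not adjusted over the results tested, so it does not exclude chance. Regroupings that call more than the real one point to a structure of the arrays.

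Probe sets without a single gene to their name, which the gene tests do not use, held 230 calls between iPS and ES cells at day 0, 126 higher and 104 lower. Of 13767 such probe sets, 52 differed at least 2-fold and 37 of those were lower.

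Among the day 5 arrays, ES replicate 1 lay at 6.8 on the leading component against -30.9 and -29.5 for its group, and ST8 replicate 2 at 22.6 against -26.7 and -26.9. Labelling of a single array is argued against for the ES sample, because its deviation across genes recurred on the amplified array of the same number at r = 0.65. Carry-over of undifferentiated cells in ES replicates 2 and 3 would raise every pluripotency gene by a like share of its day 0 level, but the highest share was 38.8 times the median: 21.9% for Pou5f1, 17.3% for Utf1 and 15.7% for Nanog against 0.476% for Dppa5a, with a median of 0.565% that lies near 0 and inflates the ratio (quartiles -0.195% to 2.25%). Nothing decides the cause for ST8 replicate 2, which has no amplified counterpart, and a difference in the stage reached by each culture stays open and was not tested.

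Meg3, Rian and their noncoding neighbours were lower in both clones at day 0. A variant under the probes of a single transcript is argued against by 23 of 50 probe sets of the domain being lower by at least 1 in both clones, with 0 higher by as much. Loss of the whole domain on both alleles is argued against by Dlk1, which rose from day 0 to day 5 by at least 1.15 in both clones. Dlk1 lies at an end of the domain, so its rise cannot decide on a loss limited to the noncoding stretch. Silencing or loss of the maternal copy may account for the pattern, as a hypothesis that expression alone does not test. Whether fibroblast RNA adds to Meg3 on the iPS day 0 arrays cannot be told apart: over 6 arrays Meg3 correlated with the fibroblast list at r = 0.722 (exact permutation p = 0.0681; rho = 0.771, p = 0.103), and at r = 0.511 without the 2 arrays farthest from the median. Day 0 cells were sorted as Sox2 bright, but how far that sort removed fibroblasts was not measured. Col1a1, an abundant fibroblast gene, stood at 9.78 in ST5 and 9.79 in ST8 at day 0, and at 9.56 in ES cells.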

How the results depend on the processing

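The setting that leaves out ES day 5 replicate 1 and ST8 day 5 replicate 2 together was chosen after the results were seen; the others were planned. Signal over background on the arrays limits dim genes, and 3 arrays per group limit all counts. Of 861 named-gene values, the direction and the side of the threshold were the same for 849 after a further quantile normalization, 847 with a common median, 827 with all 30 arrays, 838 with an intensity trend and robust spread, 829 with the replicate block, 721 with only the groups of a contrast, and 703 of the 705 left with dim genes out. The probe choices left all 861 the same but touch only 8 and 3 of the 288 named genes. Leaving out single arrays kept 5439 of 6177 values, with 661 no longer past the threshold and 0 reversed.

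With a least log2 difference of 1, which removes smaller calls by construction, counts were 1314 in the ES response, 2210 in ST5, 1437 in ST8, 933 in ES cells after amplification, 266 for foregut against ENDM1-negative cells and 611 against ES day 5. They were 52 for iPS against ES cells at day 0, 94 at day 5, 71 for the difference of responses, 1 and 258 for ST8 against ST5 at day 0 and day 5, and 42 and 27 for calls shared by the clones. With only the groups of a contrast, fewer arrays estimate the spread, and for comparisons at a single day it no longer pools day 0 with day 5 groups. At day 0 and day 5, iPS against ES cells then gave 1737 and 140, ST8 against ST5 6 and 3, and calls shared by the clones 734 and 30. The count for iPS against ES cells thus rose at day 0 and fell at day 5, which fewer arrays alone would not give. With dim genes left out, ST8 against ST5 at day 0 gave 23 and calls shared at day 5 88; with the replicate block the former gave 5, and with all 30 arrays foregut against ENDM1-negative cells gave 2467. The cause was not tested for these.

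With both day 5 arrays left out, iPS against ES cells at day 5 gave 5105 genes, the difference of responses 2840, ST8 against ST5 at day 5 6625 and calls shared by the clones at day 5 942. The rise is built into the choice of arrays, since each lay apart from its group. Kit in the ES response turned from 0.28 to -0.29 (adjusted p = 0.0295) in that setting; Kit was used for sorting. List shifts past the threshold numbered 126, and 32 with an estimated correlation.

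Across genes, the ES response correlated with that of ST5 at 0.754 by Spearman and with that of ST8 at 0.813 (0.942 with dim genes left out). With the amplified response it was 0.774 by Spearman, 0.933 with dim genes left out and 0.915 over genes called in either response, and the amplified response with foregut against ENDM1-negative cells gave 0.271 and 0.443.

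Leaving out each array in turn, counts ranged from 6694 to 7325 in ES cells, 8683 to 9435 in ST5, 7114 to 7761 in ST8 and 4501 to 5001 after amplification. They ranged from 489 to 871 for iPS against ES cells at day 0 and 233 to 4461 at day 5, 173 to 1744 for the difference of responses, 3 to 21 and 675 to 5951 for ST8 against ST5, 985 to 1174 for foregut against ENDM1-negative cells and 3381 to 4928 against ES day 5. Calls shared by the clones ranged from 194 to 300 and 69 to 826, list shifts from 122 to 135, and the correlations from 0.798 to 0.896, 0.889 to 0.928, 0.866 to 0.893 and 0.296 to 0.375 in the order above. Arrays of the same number in different groups did not correlate above 0.1 in all 3 replicates of any contrast, so the numbers were not taken as pairs.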

Other observations

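The split counts, the copy gain test and the neighbour test were chosen before the results were seen; the neighbour draw matched for expression only after. Imprinted genes moved widely as ES cells differentiated. Of 24 paternally expressed genes 12 rose and 3 fell (13 and 3 adjusted over the list alone; camera adjusted p = 0.00201, and adjusted p = 0.214 with an estimated correlation), the growth factor gene Igf2 by 3.13 ± 0.17 and Peg3 by 2.88 ± 0.14, with Sfmbt2 at -3.26 ± 0.11. Of 16 maternally expressed genes 9 rose and 3 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.0276, and adjusted p = 0.384 with an estimated correlation), Asb4 by 3.43 ± 0.23 and the adaptor gene Grb10 by 2.22 ± 0.15. Both list calls were lost with dim genes left out (adjusted p = 0.07 and 0.0807), and the maternal one without ES day 5 replicate 1 (0.0608). Epithelial genes rose in 9 of 14 cases and fell in 1 (10 and 2 adjusted over the list alone), the keratins Krt18 by 3.39 ± 0.20 and Krt8 by 3.08 ± 0.21 (camera adjusted p = 0.000808, and adjusted p = 0.461 with an estimated correlation). Immediate early and heat shock genes fell in 10 of 13 cases and rose in 1 (10 and 1 adjusted over the list alone), Fosb by -3.17 ± 0.27 and Fos by -2.44 ± 0.20 (camera adjusted p = 3.24e-05, and adjusted p = 0.0708 with an estimated correlation). p53 targets fell in 7 of 11 and rose in 1 (8 and 1 adjusted over the list alone; camera adjusted p = 0.0128, and adjusted p = 0.487 with an estimated correlation; 0.0945 with dim genes left out).

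Lists of other fates did not pass camera's test in the ES response, though members moved. Of 11 epiblast genes 4 rose (4 adjusted over the list alone; adjusted p = 0.125), Otx2 by 2.53 ± 0.14, and of 15 primitive streak genes 6 rose and 2 fell (adjusted p = 0.118), Lhx1 rising by 3.45 ± 0.38. Rises and falls were 7 and 2 of 19 in visceral endoderm (0.214), 3 and 1 of 12 in parietal endoderm (0.66), 5 and 0 of 18 in neural ectoderm (0.208), 0 and 3 of 10 in surface ectoderm (0.491), 4 and 2 of 16 in mesoderm and heart (0.356), 2 and 3 of 10 in endothelium (0.198) and 1 and 0 of 10 in blood (0.377). They were 3 and 0 of 8 in trophoblast (0.0867), 0 and 0 of 11 in posterior Cdx and Hox genes (limma; 0.423), 1 and 1 of 4 sex-linked genes (0.972), 8 and 3 of 16 in glycolysis (0.117), 1 and 4 of 18 in cholesterol synthesis (0.161), 2 and 3 of 10 mesenchymal genes (0.936), 4 and 4 of 9 Wnt targets (0.634) and 4 and 2 of 9 Nodal and activin targets (0.605), the values in parentheses being adjusted p. Adjusted over the list alone, the counts of these lists were the same except for 4 rises in trophoblast, 2 rises in sex-linked and 3 in mesenchymal genes. In foregut against ES cells at day 5, immediate early genes were higher in 9 of 13 cases and lower in 1, Fosb by 1.86 ± 0.13 (9 and 1 adjusted over the list alone; camera adjusted p = 0.000158, and adjusted p = 0.047 with an estimated correlation), and parietal endoderm genes in 7 of 12, the laminin gene Lama1 by 1.94 ± 0.11 (9 adjusted over the list alone; camera adjusted p = 0.000148, and adjusted p = 0.047 with an estimated correlation).

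Sex-linked genes differed between lines at day 0, 2 of 4 being higher in iPS cells (2 adjusted over the list alone), Uty by 0.74 ± 0.08 and Eif2s3y by 0.51 ± 0.07 (camera adjusted p = 0.000143, and adjusted p = 0.0214 with an estimated correlation), while Kdm5d at 0.11 and Xist at 0.17 did not pass the test. Foregut had more Kdm5d RNA than ES cells at day 5, by 3.08 ± 0.13, and less of Eif2s3y and Uty, by -1.43 ± 0.09 and -1.38 ± 0.10. Arrays of ES day 5 cells with the same number with and without amplification correlated across genes at 0.65, 0.447 and 0.285 in their deviation from the group, so the samples may share RNA and the amplified response is not an independent repeat.

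Nr1h5 and Sycp1, which lie side by side, were higher in both clones at day 0. A gain of copies of the wider region is argued against by the 10 measured neighbours, 5 on each side, whose median difference was 0.06 (quartiles -0.07 to 0.12). All of them lie outside the pair, so they cannot decide on a gain limited to Nr1h5 and Sycp1. Genes called between iPS and ES cells in one direction lay next to each other in 92 pairs, 39 of them in the Meg3 domain and 53 outside, against a median of 24 and a highest of 41 in 1000 random draws, and a median of 25 and a highest of 41 in draws matched for expression. Regional differences in regulation are a candidate explanation for these 92 pairs; probes that read overlapping transcripts were not tested.

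For groups of 3 against 3 arrays, 10 splits are too few for a share under 0.05. In each, the real split alone (1 of 10) gave its count, with 0 adjusted calls by limma in every other split. Fitted on these arrays alone, the real adjusted counts were 6990 in ES cells, 9741 in ST5, 6728 in ST8, 4664 in ES cells after amplification, 1562 for foregut against ENDM1-negative cells, 3747 for foregut against ES day 5, and 6 at day 0 and 3 at day 5 for ST8 against ST5. In the same order, genes with an unadjusted p under 0.05 in the real split and in the highest other split were 8579 and 782, 10768 and 398, 8542 and 460, 6886 and 496, 4473 and 780, 6899 and 930, 2051 and 2110, and 4615 and 2477. By that count another split reached more genes than the real one for ST8 against ST5 at day 0 alone. For iPS against ES cells at day 0, 1 of 84 splits gave as many as the real 1464, with a highest other of 14. No other split came near the real count, but that share was not adjusted over the results tested, and the splits do not measure the spread between lines. At day 5, 4 of 84 gave as many as the real 51, and the highest other gave 1582. That share lies just under 0.05 and was not adjusted over the results tested, so it does not exclude chance. A regrouping that calls many times the real count points to a structure of the arrays. Calls shared by the clones were reached by 1 of 100 groupings at day 0 (real 734, highest other 692) and 2 of 100 at day 5 (real 30, highest other 42). Both shares are under 0.05. At day 0 no other grouping drawn reached the real count, though the highest other came near it, and at day 5 another grouping exceeded the real count. These shares were not adjusted over the results tested, so they do not exclude chance. List shifts were reached by 5 of 100 groupings (real 126, median of the others 87, highest other 144), so chance is not excluded by this count. That redraw mixes day 0 and day 5 arrays, so redrawn groups still carry part of the differentiation change. It therefore cannot tell how many list calls at the preset correlation arise without any effect.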
